A study of Mus musculus with 6 samples.

How the data were processed

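Gene expression was measured by RNA sequencing in 6 libraries from tibialis anterior muscle of C57BL/6 mice. Per the labels, the muscle was injured by injection of 50 µl of 10 µM cardiotoxin, a snake venom toxin that destroys muscle fibres and starts regeneration, at 5 weeks of age. Per the labels, 6.25 µg of pcDNA3.1 plasmid was then delivered with an in vivo transfection reagent and the muscle was taken on day 7. The labels put 3 libraries in a control group and 3 in a group with gain of function of the long non-coding RNA Linc-smad7, called L7. Polyadenylated RNA was selected with poly-T beads before library preparation with a kit from the NEBNext Ultra RNA line, per the labels. The strand setting of the read counting is not given in the sources used here.

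The deposited FPKM table (fragments per kilobase of gene, scaled to library depth, 1 value per gene and library) was made by the authors and covers 52369 genes. The submitters' processing notes name the mouse build mm10 and the tools Bowtie2 2.2.3, TopHat2 2.0.12, HISAT2 2.0.4 and DESeq 1.12.0, without saying which tool made which value. The counting program and the annotation are not given in the sources used here. A second table deposited by the authors compares the groups and holds, per the file headers, a mean normalised signal per group (read counts divided by size factors), a log2 fold change, a p-value and an adjusted p-value. Its column of significant genes marked 359 genes, and these were exactly the genes with an unadjusted p under 0.05. The authors also deposited p-values of over-represented Gene Ontology terms and KEGG pathways, with numbers of genes per term. The enrichment tool is not given in the sources used here.

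Gene symbols were found for 51633 genes and coordinates for 51719 genes in the GENCODE M21 annotation of the same build, matched by Ensembl identifier. A further 457 genes have identifiers of the kind of Novel00250, which carry no coordinates here. Because the authors counted whole reads, the steps between low FPKM values and the size factors behind the group means gave back the reads per gene, and 152091 of 152096 values above 0 (99.997%) came out within 0.05 of a whole number. These reads in genes ranged from 19420012 to 24663153 per library and are the depth behind each value. They were used for depth, read numbers and shares of reads, for the sex-linked reads behind the sex covariate, and for limma voom as an alternative.

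The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), two-sided, with group as the only factor. It covered the 14788 genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The groups, gene lists, tests, first alternatives and the rule for named genes were fixed before the data were examined. Of 36 lists, 3 (sex-linked genes, mitochondrial transcripts and non-polyadenylated histones) served as checks and are given as values, epidermis had under 5 measured members, and the other 32 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Single genes near Smad7 and list means also had an exact permutation test, whose smallest two-sided p with 3 libraries against 3 is 0.1. Genes with a site for the seed of miR-125b, the microRNA named in the series title, were found by searching the longest annotated 3 prime UTR of each gene for CTCAGGG. Standard errors of list medians came from 1000 bootstrap draws over members, so they do not measure the spread between libraries. On simulated reads for 14788 genes with 200 genes changed, at a dispersion of 0.05, limma recovered 27.0% of genes changed 2-fold, 98.5% of genes changed 4-fold and 99.5% of genes changed 8-fold, with 5, 16 and 13 false calls in the same order, and with no gene changed it made 3 false calls. The simulation drew each gene independently around the mean control profile and held no library that stood apart from the others. Its recovery rates therefore do not carry over to the real libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.

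The rule for named genes takes Smad7 and its annotated neighbours within 500 kb, then up to 10 genes in each direction that passed limma with groups that did not overlap or, where fewer passed, those of smallest unadjusted p. It adds, in each list, up to 4 members that passed limma or the deposited table's adjusted p, and otherwise the 2 members of highest mean FPKM, and finally the 5 genes of smallest adjusted p in each direction of the deposited table. Genes named only by Gm and digits, by a name ending in Rik or without a symbol are outside the second and last parts. Novel00250, Gm10800, Gm23935, Gm24270, Gm5559, Isg15, the other Y-linked genes beside Eif2s3y and the list members beyond the rule were named after their values were seen. Alternatives were other pseudocounts, expression filters and scalings, a replicate block, limma without a trend or with array weights, and leaving out each library. The identity of 1 gene called under alternatives is not reported here. Added after seeing the data were limma voom on the recovered reads, sex as a covariate, removal of small and non-polyadenylated gene types, and median of ratios scaling without L7 replicate 3. No source says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries. No gene is called the overexpressed transcript, because no name in the tables is Linc-smad7.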

Results

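The data were 6 RNA sequencing libraries from tibialis anterior muscle of mice taken on day 7 after cardiotoxin injury, 3 labelled control and 3 with Linc-smad7 gain of function (L7). The reads in genes came to 20897439, 19420012 and 24663153 in the control libraries and to 22179456, 20725423 and 21187694 in the L7 libraries. L7 replicate 3 stood apart from the other 5 libraries. Its correlation over genes with them was 0.920 to 0.951, against 0.979 to 0.989 among the others, and the first principal component, with 67% of the variance, held it at 72.2 while the others lay between -29.0 and -3.80. The 10 genes with most reads took 14.1% of its reads, against 6.60% to 8.40% elsewhere. Mitochondrial transcripts took 4.20% of its reads, against 1.85% to 2.51% elsewhere. Median of ratios scaling gave it a factor of 0.769, against 1.025 to 1.089 for the others, and moved the median log2 difference of all genes from -0.15 to -0.0015. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in control replicates 1 and 3 and L7 replicate 1. The other 3 libraries had Xist, the RNA of the inactive X chromosome, at 92.0, 90.9 and 40.7 FPKM and at most 1 read of each Y-linked gene.

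Around Smad7, the gene of an inhibitor of TGF-beta signalling, 1 neighbouring transcript was higher in the L7 libraries and Smad7 itself was not. Gm20544 (ENSMUSG00000092569) was at 2.04 ± 0.441 FPKM (SD, n = 3) in control and 10.6 ± 5.13 FPKM (SD, n = 3) in L7 libraries, and each L7 value (10.7, 15.7 and 5.47 FPKM) lay above each control value (1.87, 2.54 and 1.70 FPKM). It is annotated as a processed transcript on the minus strand of chromosome 18 from 75365332 to 75367088 (mm10), 440 bp from Smad7 on the plus strand at 75367529 to 75395935. Smad7 was at 12.1 ± 1.40 FPKM (SD, n = 3) in control and 10.6 ± 3.30 FPKM (SD, n = 3) in L7 libraries. The unannotated gene Novel00250 was at 1.98 ± 0.207 FPKM (SD, n = 3) in control and 16.1 ± 8.12 FPKM (SD, n = 3) in L7 libraries.

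This check asks whether the locus that gives Linc-smad7 its name differed between the groups. In limma the log2 difference of Gm20544 was 1.84 ± 0.34 (SE), with p = 0.000792 unadjusted and an adjusted p of 0.580, and its exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Novel00250 had a log2 difference of 2.42 ± 0.31 (SE) and a limma adjusted p of 0.468. In the authors' deposited table Gm20544 was 5.67-fold higher with an adjusted p of 0.0449, and Novel00250 was 8.88-fold higher with an adjusted p of 0.0229. Smad7 had a log2 difference of -0.20 ± 0.22 (SE), a limma adjusted p of 0.657 and an exact permutation p of 0.5. Of the 18 annotated genes within 500 kb of Smad7, 10 entered the test and none passed it by limma. Ctif, Dym, Lipg, Zbtb7c, Rpl17 and the small nucleolar RNA Gm23301 had overlapping groups. The snoRNA genes Gm23301 and Snord58b lie within the span of Rpl17, and how the counting split reads there is not given in the sources used here. BC031181 and the small nucleolar RNA Snord58b had each L7 value below each control value. For Snord58b this rests on few reads, 17, 10 and 21 in control and 11, 8 and 5 in L7 libraries. The reads of Gm20544 numbered 27, 34 and 29 in control and 164, 225 and 80 in L7 libraries. With array weights in limma the adjusted p of Gm20544 was 0.0181, and over all its alternatives the adjusted p ranged from 0.0181 to 0.873.

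**Figure D1:**
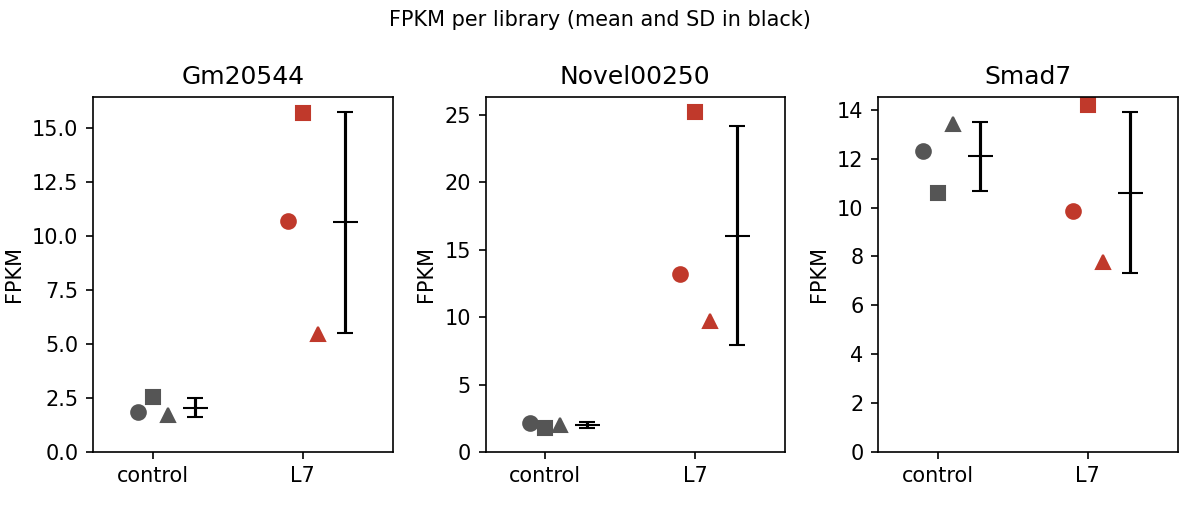
FPKM of Gm20544, Novel00250 and Smad7 in each library (circle, square and triangle for replicates 1, 2 and 3; grey for control, red for L7; black for mean and SD, n = 3). Gm20544 and Novel00250 are higher in each L7 library than in each control library, while the Smad7 values overlap.

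Genes of the interferon response, the antiviral programme switched on by interferons, were lower in the L7 libraries. All 25 measured members had negative log2 differences, with a median of -0.71 (-0.56 relative to all genes). In 23 of them the groups did not overlap, each time with L7 below control, where chance gives 2.5 members without overlap in either direction. Over all genes the groups did not overlap in 19.2%. The members moved together, with an estimated correlation of 0.75, so they are not 23 separate observations. For the mean of the list the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Cxcl10, a chemokine that attracts T cells, was at 319 ± 75.2 FPKM (SD, n = 3) in control and 118 ± 31.0 FPKM (SD, n = 3) in L7 libraries. Isg15, a ubiquitin-like antiviral protein, was at 405 ± 47.2 FPKM (SD, n = 3) against 226 ± 38.6 FPKM (SD, n = 3). Bst2 was at 1150 ± 32.1 FPKM (SD, n = 3) against 836 ± 108 FPKM (SD, n = 3), and Irf7, a transcription factor of the response, was at 743 ± 161 FPKM (SD, n = 3) against 564 ± 82.6 FPKM (SD, n = 3), with overlapping groups. Cxcl11, a chemokine related to Cxcl10, outside the list and annotated as a polymorphic pseudogene, was at 7.89 ± 1.56 FPKM (SD, n = 3) against 2.62 ± 0.788 FPKM (SD, n = 3).

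The list fell in camera with an adjusted p of 1.74e-15 at the preset correlation, and its adjusted p = 0.403 with an estimated correlation, so the call was lost there. No member passed limma over all genes, and 22 of 25 members fell when adjusted over the list alone. Cxcl10 had a log2 difference of -1.43 ± 0.27 (SE), and its limma p was 0.0181 adjusted over the list alone and 0.580 adjusted over all genes. Without L7 replicate 3 all 25 members were still lower, and the list median relative to all genes was -0.53. The authors' deposited table had 11 of the 25 members lower and 0 higher at an unadjusted p under 0.05.

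**Figure D2:**
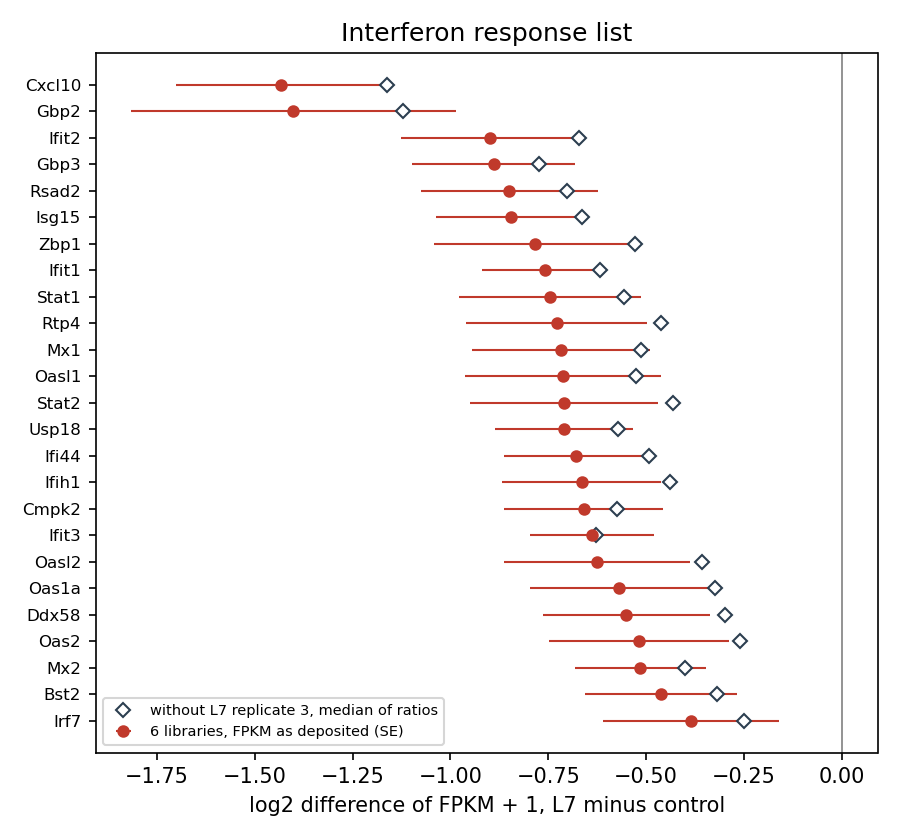
Log2 difference of FPKM + 1, L7 minus control, for the 25 members of the interferon response list (red circles with SE from limma, 6 libraries; open diamonds without L7 replicate 3 after median of ratios scaling). All 25 members lie below 0 on both scales.

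Inflammatory cytokines and chemokines were also lower, with 21 of 21 measured members negative and a median log2 difference of -0.96 (-0.81 relative to all genes). Ccl7, a monocyte chemoattractant, was at 236 ± 47.7 FPKM (SD, n = 3) in control and 110 ± 57.3 FPKM (SD, n = 3) in L7 libraries, and Cxcl9 was at 245 ± 92.9 FPKM (SD, n = 3) against 90.2 ± 44.4 FPKM (SD, n = 3). The list fell in camera with an adjusted p of 1.84e-06, and its adjusted p = 0.636 with an estimated correlation. None of its members passed limma over all genes or adjusted over the list alone, and without L7 replicate 3 on the median of ratios scale its median was -0.41. Il1rl1, the receptor of interleukin 33, was at 7.86 ± 1.53 FPKM (SD, n = 3) against 2.56 ± 1.54 FPKM (SD, n = 3), with an adjusted p of 0.0229 in the authors' deposited table and 0.580 in limma. Cell cycle genes were lower in 30 of 30 members, with a median of -0.52 (-0.37 relative to all genes), a camera adjusted p of 0.000499 and an adjusted p = 0.753 with an estimated correlation. Without L7 replicate 3 on the median of ratios scale the cell cycle median was -0.06. Pcna, a DNA replication clamp, was at 119 ± 11.5 FPKM (SD, n = 3) against 88.2 ± 26.5 FPKM (SD, n = 3). Top2a, a topoisomerase of dividing cells, was at 56.5 ± 4.89 FPKM (SD, n = 3) against 37.0 ± 19.2 FPKM (SD, n = 3).

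Genes of the adult muscle fibre were higher in the L7 libraries, most of all in L7 replicate 3. All 23 measured members of the adult fast sarcomere list had positive log2 differences, with a median of 0.80 (0.95 relative to all genes). Acta1, the skeletal muscle actin, was at 8170 ± 2120 FPKM (SD, n = 3) in control and 19000 ± 12800 FPKM (SD, n = 3) in L7 libraries, with 33700 FPKM in L7 replicate 3. All 18 glycolysis and glycogen genes and all 25 oxidative phosphorylation genes were higher, with medians of 0.67 and 0.36 (0.83 and 0.52 relative to all genes), as were 15 of 16 fatty acid oxidation genes, with a median of 0.38 (0.53 relative to all genes). Aldoa, a glycolytic aldolase, was at 2600 ± 524 FPKM (SD, n = 3) against 5280 ± 3600 FPKM (SD, n = 3), and Eno3, the muscle enolase, was at 1900 ± 240 FPKM (SD, n = 3) against 3930 ± 2360 FPKM (SD, n = 3).

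Mitochondrial transcripts and the 4 measured histone genes had been set as checks of RNA quality. In L7 replicate 3 their medians lay 1.33 and 1.44 above the mean of the other L7 libraries on the median of ratios scale. The adult fast sarcomere list lay 1.96 above it and the oxidative phosphorylation list 1.20, so these checks cannot tell RNA quality from fibre content here. Not every mitochondrial transcript rose in L7 replicate 3. On FPKM as deposited mt-Co2 was at 1310, against 2780 and 2100 in L7 replicates 1 and 2, and mt-Co3 and mt-Atp6 lay between those libraries. The adult fast sarcomere, glycolysis, oxidative phosphorylation and fatty acid oxidation lists rose in camera with adjusted p-values of 2.07e-17, 8.91e-13, 8.91e-13 and 6.3e-07. With an estimated correlation the adjusted p = 0.403, 0.421, 0.528 and 0.566 in the same order. Without L7 replicate 3 on the median of ratios scale their medians were 0.39, 0.28, 0.13 and 0.15. All L7 values lay above all control values in 12 of 23, 10 of 18, 6 of 25 and 4 of 16 members, in the same order. In 1 fatty acid oxidation member all lay below. Without L7 replicate 3, 23, 15, 19 and 12 members were still higher. The authors' deposited table had 0 members of each list higher at an unadjusted p under 0.05. Of the members, 1 fatty acid oxidation gene passed limma adjusted over the list alone and it was lower, Angptl4, an inhibitor of lipoprotein lipase, at 53.5 ± 6.85 FPKM (SD, n = 3) in control and 27.5 ± 3.21 FPKM (SD, n = 3) in L7 libraries, with a limma p of 0.000505 and an adjusted p of 0.580 over all genes. The slow fibre list rose with a median of 0.27 and a camera adjusted p of 0.00097 (adjusted p = 0.275 with an estimated correlation), and its median without L7 replicate 3 on the median of ratios scale was 0.28. Its member Mybpc1, a myosin-binding protein, was at 560 ± 124 FPKM (SD, n = 3) against 975 ± 289 FPKM (SD, n = 3), and Mb, the myoglobin gene, had overlapping groups.

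**Figure D3:**
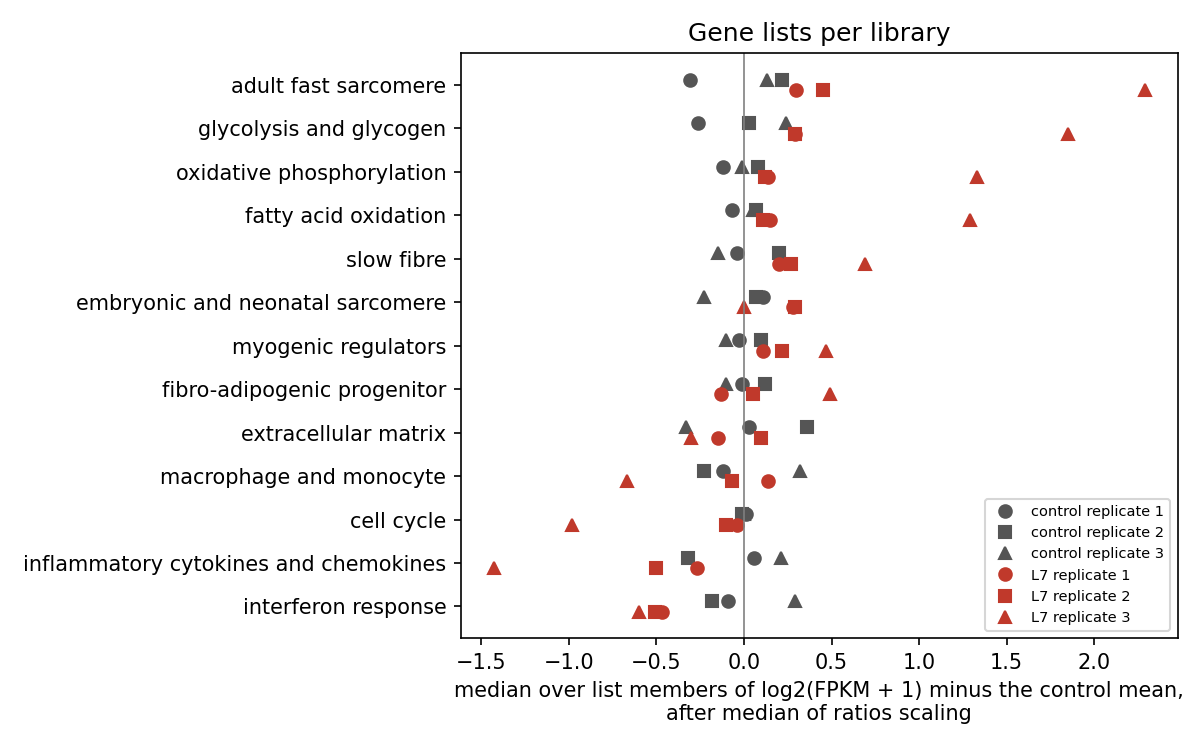
Median over the members of 13 gene lists of log2(FPKM + 1) minus the control mean, per library, after median of ratios scaling (grey for control, red for L7; circle, square and triangle for replicates 1, 2 and 3). L7 replicate 3 lies at 2.29 for the adult fast sarcomere list and at -0.98 for the cell cycle list, while all 3 L7 libraries lie between -0.60 and -0.47 for the interferon response list.

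The myogenic regulators rose in camera with a median of 0.065 (adjusted p 0.0112, and adjusted p = 0.403 with an estimated correlation), with 8 members higher and 7 lower and a median of 0.16 without L7 replicate 3 on the median of ratios scale. Nfix was at 171 ± 29.9 FPKM (SD, n = 3) in control and 201 ± 11.6 FPKM (SD, n = 3) in L7 libraries, and Mef2c was at 142 ± 19.2 FPKM (SD, n = 3) against 166 ± 10.8 FPKM (SD, n = 3). The embryonic and neonatal sarcomere list was called higher (adjusted p 0.00615, and adjusted p = 0.403 with an estimated correlation), though its median was -0.014, its mean was 0.11 and 9 of 16 members were lower. Its median was 0.16 with median of ratios scaling and 0.26 when L7 replicate 3 was also left out, and with quantile normalization it was not called (adjusted p 0.102). Neither list was called without control replicate 3 (adjusted p 0.0598 for both) or without L7 replicate 2 (0.0591 for both). Its member Actc1, the cardiac actin that regenerating muscle also makes, was at 1900 ± 406 FPKM (SD, n = 3) against 3230 ± 359 FPKM (SD, n = 3), and each L7 library lay above each control library. The satellite cell and myoblast list, the fusion and differentiation list and the neuromuscular junction list had camera adjusted p-values of 0.519, 0.283 and 0.265. Without L7 replicate 3 the neuromuscular junction list was called higher, with an adjusted p of 0.0281, and without control replicate 1 the fusion list was, with 0.0488. Igf2, a growth factor on the list of literature targets of miR-125b, was at 556 ± 176 FPKM (SD, n = 3) against 638 ± 67.7 FPKM (SD, n = 3). That list had 4 members higher and 12 lower and a camera adjusted p of 0.474. The IGF and growth signalling list had 10 members higher and 10 lower and an adjusted p of 0.0548, and it was called higher without L7 replicate 3 (adjusted p 0.00369), without control replicate 1 (0.0168), without control replicate 2 (0.0148) and with median of ratios scaling (0.0124).

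Other cell types were compared by their marker lists. Adipocyte genes rose with a median of 0.50 (camera adjusted p 8.47e-05, and adjusted p = 0.275 with an estimated correlation), Schwann cell and nerve genes with a median of 0.16 (adjusted p 0.00277, and adjusted p = 0.275 with an estimated correlation) and circadian clock genes with a median of 0.14 (adjusted p 0.00615, and adjusted p = 0.403 with an estimated correlation). The clock list was not called without L7 replicate 3 (adjusted p 0.0898) or without control replicate 3 (adjusted p 0.0598). Without L7 replicate 3 on the median of ratios scale these 3 medians were 0.31, 0.14 and 0.23. In the adipocyte, Schwann cell and clock lists 7 of 9, 8 of 9 and 9 of 14 members were higher in the 6 libraries. None of them passed limma over all genes or adjusted over the list alone. Macrophage and monocyte genes were lower in 23 of 28 members, with a median of -0.35 and a camera adjusted p of 0.430. That median was 0.06 without L7 replicate 3 on the median of ratios scale. The most abundant macrophage list member Apoe was at 5210 ± 257 FPKM (SD, n = 3) against 5280 ± 798 FPKM (SD, n = 3). Neutrophil genes were lower in 9 of 10 members with a median of -0.79, T and NK lymphocyte genes in 16 of 19 with a median of -0.42, and dendritic cell and antigen presentation genes in 12 of 13 with a median of -0.48. Without L7 replicate 3 on the median of ratios scale these medians were -0.05, -0.15 and -0.35. Their camera adjusted p-values were 0.193, 0.0548 and 0.316, and that of the B lymphocyte list, with a median of 0.095, was 0.161. The T and NK lymphocyte list was called lower in 7 of its alternatives, with adjusted p-values from 3.55e-05 without control replicate 2 to 0.0328 with median of ratios scaling. Extracellular matrix, fibro-adipogenic progenitor, tendon, endothelium, and pericyte genes had adjusted p-values of 0.469, 0.306, 0.184, 0.133 and 0.0708. The extracellular matrix list was called lower with sex as a covariate (adjusted p 0.0486), and with median of ratios scaling the endothelium list was called higher (0.0452) and the neutrophil list lower (0.0411). Col1a1, a fibrillar collagen, was at 7380 ± 1650 FPKM (SD, n = 3) against 7150 ± 1900 FPKM (SD, n = 3). The lists for TGF-beta and BMP signalling, muscle atrophy, erythroid cells and platelets, and immediate early and stress genes had adjusted p-values of 0.469, 0.371, 0.748 and 0.797. Each of these lists named by a cell type, and the extracellular matrix list, was called in at least 1 fit that left out 1 library, except the fibro-adipogenic list, and the macrophage list was called lower without L7 replicate 1 (adjusted p 0.0169). Only 4 epidermis genes were measured, so that list was not tested. Of the check lists, mitochondrial transcripts had a median of 0.48, and 0.17 without L7 replicate 3 on the median of ratios scale, and the 4 measured histone genes had a median of 0.38, and 0.14 without it.

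Across all genes the question was which genes Linc-smad7 gain of function changed in injured muscle. No gene of 14788 passed limma at an adjusted p under 0.05, and the smallest adjusted p was 0.468. At an unadjusted p under 0.05, 244 genes were higher and 629 lower in L7 libraries, 873 in all where 739 are expected by chance. The total lay below those 739 without control replicate 1 (265), without control replicate 2 (669), without control replicate 3 (574) and with sex as a covariate (379), and above them without L7 replicate 1 (1635), without L7 replicate 2 (1234) and without L7 replicate 3 (979). Limma voom on the recovered reads, added after seeing the data, called 0 genes at an adjusted p under 0.05 and 881 at an unadjusted p under 0.05. After median of ratios scaling the split was 411 higher and 499 lower. The groups did not overlap in 19.2% of genes, where chance gives 10%. Among genes with a symbol not of the form Gm and digits, the lower genes of smallest p were Snord69, CT010467.1, Cxcl11, Angptl4, Rpph1, Trbj1-1, Lars2, Cxcl10, Mir142b and Mir7087, and none passed the adjustment. The higher ones were Padi2, Mir5620, Ttll11, Mir1a-1, Rtl8b, Igsf1, n-R5s197, Chp2, Tmod1 and Tceal5, and none passed it either. Outside that choice, Novel00250 and Gm20544 had a smaller p than Padi2, and Gm10800 had a smaller p than Snord69. Mir5620, Mir142b and Mir7087 lay near the expression floor. Mir5620, for example, was at 0.855, 0 and 0 FPKM in control and 2.42, 1.72 and 1.69 FPKM in L7 libraries. Their unadjusted p in the authors' deposited table was 0.214, 0.0387 and 0.248 in the same order. Padi2, an enzyme that converts arginine to citrulline, was at 23.3 ± 4.12 FPKM (SD, n = 3) in control and 50.1 ± 12.8 FPKM (SD, n = 3) in L7 libraries. Rpph1, the RNA of ribonuclease P, which is not polyadenylated, was at 6.46 FPKM or more in each control library and at 2.83, 1.66 and 0.592 FPKM in the L7 libraries. Genes of transcript families such as Gbp and Ifit and copies such as CT010467.1, annotated as ribosomal RNA, share sequence, and how the counting split such reads is not given in the sources used here.

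Of 31690 genes with a p in the authors' deposited table, 9 had an adjusted p under 0.05, 2 higher and 7 lower. The higher ones were Novel00250 and Gm20544, and the lower ones were Il1rl1, Cxcl11, Rpph1, CT010467.1, Gm10800, Gm23935 and Gm24270. Of the lower ones, 4 are annotated as non-polyadenylated or microRNA types. These are Rpph1 (a ribozyme), CT010467.1 (ribosomal RNA), and Gm23935 and Gm24270 (microRNA). The authors' deposited table marked 359 genes at an unadjusted p under 0.05, 121 higher and 238 lower, which is 1.13% of the genes with a p, where uniform p-values would give 1584 genes. Of these 359 genes 258 entered limma, all with the same sign there, and 232 of them had a limma p under 0.05; both tests used the same libraries. The authors' deposited Gene Ontology enrichment counted 268 called genes with a term, more than the 9 at an adjusted p under 0.05. Its p-values thus rest mostly on genes that did not pass the adjustment. In that table response to cytokine ranked first with 4 of its called genes up and 57 down and a corrected p of 9.43e-30. Response to interferon-gamma had 0 up and 24 down, and response to interferon-beta had 0 up and 18 down. Of the 363 deposited terms at a corrected p under 0.05, 0 have the word muscle in their name. Skeletal muscle tissue development, named in the series description, had 5 genes up and 0 down and a corrected p of 0.723 in the authors' deposited table. Among pathways deposited by the authors, 6 of 197 had a corrected p under 0.05, all at 0.0115. Cytokine-cytokine receptor interaction, with 18 genes, had the smallest deposited unadjusted p, 0.000168, and HIF-1 signalling was next at 0.00017.

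Genes with a seed site for miR-125b were compared with genes without one, as the series title names that microRNA as bound by Linc-smad7. The 2161 genes with a site had a median log2 difference of -0.13 and the 10619 genes without a site had -0.16. Camera gave p = 0.445 at the preset correlation and p = 0.874 with an estimated correlation, so the sets did not differ by more than the spread.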

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

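Limma voom on recovered reads, sex as a covariate, removal of small gene types, and median of ratios without L7 replicate 3 were chosen after seeing the data. The count of genes past the adjusted threshold in limma, 0, became 3 with array weights (Novel00250 and Gm20544 among them), 1 with median of ratios without L7 replicate 3, and 0 to 1 over the fits that left out a library, the 1 being Gm5559 without L7 replicate 1. It was 0 in the other settings, voom included. Array weights gave Gm20544 a log2 difference of 2.19 and an adjusted p of 0.0181. Genes higher at an unadjusted p under 0.05 were 244, and 462 with no filter, 411 with median of ratios, 465 with quantile normalization, 391 with the replicate block, 613 with array weights, 417 with voom, 94 with the sex covariate, 493 with median of ratios without L7 replicate 3, and 55 (without control replicate 1) to 426 (without L7 replicate 1) when a library was left out. Lower genes were 629, and 1100 with no filter, 1003 with array weights, 285 with the sex covariate, and 210 to 1209 when those same libraries were left out. Apart from no filter testing more genes, the cause was not tested. The 13 list calls became 0 with the correlation estimated per list and 0 with fry, whose lowest adjusted p was 0.510, and 12 to 20 when a library was left out. The interferon response list kept its direction and its side of the threshold in its 14 other camera settings at the preset correlation, with medians from -0.80 to -0.53. Over these settings of all 32 lists, interferon response included, 373 list results kept their direction and call, 38 gained a call, 8 lost one and 29 changed direction. The 9 genes of the authors' deposited table became 1 at an adjusted p under 0.01. The replicate block gave 0 adjusted calls, 1178 genes at an unadjusted p under 0.05 against 873, and 14 lists, with the extracellular matrix list added (adjusted p 0.0295). Deviations of same-numbered libraries correlated at 0.32, -0.07 and 0.09, and not every library correlated best with its own number. These values gave no sign of a pairing. They cannot exclude it, because deviations within a group sum to 0 and L7 replicate 3 weighs on them. Control replicate 3 had reads of Y-linked genes and L7 replicate 3 had at most 1 read of each, which argues against a shared animal for that number.

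Lists that changed sign were ones that camera had not called. For genes this says nothing, as the main limma test had called none. With array weights the values that changed sign were Smad7 0.036, Ctif 0.084, Mb -0.27, Tgfb1 0.031, Col1a1 0.12, Pcolce 0.028, Lyz2 0.35, Eng 0.041, Cdh5 -0.056 and mt-Cytb -0.02. With median of ratios they were Ctif 0.094, Sqstm1 0.17, Col1a1 0.12, Col3a1 0.045, Pcolce 0.15, Thbs4 0.048, Lyz2 0.10, Eng 0.12 and the erythroid list -0.11. With voom they were Ctif 0.12, Sqstm1 0.19, Col1a1 0.12, Col3a1 0.046, Pcolce 0.15, Thbs4 0.052, Lyz2 0.091, Eng 0.13 and the erythroid list -0.17. With quantile normalization they were Ctif 0.10, Mylpf -0.14, Sqstm1 0.006, Pcolce 0.002, Apoe -0.21, Eng 0.045 and the erythroid list -0.16. With no filter they were the B lymphocyte list -0.071 and the erythroid list -0.16. With the sex covariate they were the macrophage list -0.13, Lyz2 0.14, Cdh5 -0.006 and Xist -0.25. With median of ratios without L7 replicate 3 they were the lists for atrophy -0.048, TGF-beta -0.005, miR-125b targets -0.023, matrix -0.011, fibro-adipogenic cells -0.071, macrophages 0.061, endothelium -0.002 and erythroid cells -0.25, and Smad7 0.01, Ctif 0.18, Mb -0.38, Tgfb1 0.037, Col1a1 0.17, Pcolce 0.071 and Lyz2 0.39. A list's sign is that of its test, which can differ from that of its median. Over the fits that left out a library the list medians ranged from -0.078 to -0.013 (atrophy), -0.37 to -0.034 (TGF-beta), -0.36 to -0.052 (miR-125b targets), -0.43 to -0.042 (matrix), -0.10 to 0.10 (fibro-adipogenic), -0.68 to 0.03 (macrophage), -0.99 to -0.029 (dendritic), -0.046 to 0.085 (endothelium), -0.53 to 0.35 (erythroid) and -0.28 to -0.072 (immediate early). The genes ranged from -0.20 to 0.15 (Ctif), -0.41 to 0.87 (Mb), -0.084 to 0.079 (Sqstm1), -0.048 to 0.41 (Igf2), -0.45 to 0.006 (Tgfb1), -0.25 to 0.14 (Col1a1), -0.091 to 0.04 (Pcolce), -0.099 to 0.12 (Apoe), -0.38 to 0.35 (Lyz2), -0.23 to 0.36 (Ighm), -1.13 to 0.17 (H2-Ab1), -1.07 to 0.11 (Cd74), -0.17 to 0.038 (Eng), -0.14 to 0.092 (Cdh5) and -1.16 to 0.35 (Hbb-bs). The cause was not tested.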

Other observations

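The test of depth for the non-polyadenylated genes, the 3 tests of why L7 replicate 3 stood apart, that on Novel00250, the sex covariate and the fit with median of ratios without L7 replicate 3 were chosen after the result was seen, as were the margins of standard errors used to read the tests. Small and non-polyadenylated RNA genes were among the lower genes of smallest p. The higher ones included n-R5s197, annotated as ribosomal RNA, and the microRNA genes Mir5620 and Mir1a-1. Mir5620 lay near the expression floor, as did Mir142b and Mir7087 among the lower ones. Types such as ribosomal RNA, small nuclear and nucleolar RNA took 0.022%, 0.015% and 0.016% of the reads in control libraries and 0.010%, 0.010% and 0.006% in L7 libraries. Snord69, a small nucleolar RNA, was at 8.28 ± 1.65 FPKM (SD, n = 3) against 2.33 ± 0.505 FPKM (SD, n = 3). Rtl8b, a retrotransposon-derived gene, was at 14.3 ± 4.20 FPKM (SD, n = 3) against 38.0 ± 14.7 FPKM (SD, n = 3), and had an adjusted p of 0.0630 in the authors' deposited table and 0.580 in limma.

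Over the 137 tested genes of non-polyadenylated types, 93 were lower in L7 libraries. A general difference in the carry-over of such RNA is argued against, for the typical gene of the class, by the class median and by overlapping library levels. That median lay at -0.14 relative to protein-coding genes, less far below them than the 0.3 set beforehand. A difference in depth is argued against by a ratio of mean depths of 0.99. The composition of L7 replicate 3 stays open as a candidate explanation of the class median only, since without that library and after rescaling it lay at -0.06 relative to protein-coding genes. The share of reads in such types was nevertheless lower in each L7 library, at 0.010% in L7 replicates 1 and 2 against 0.015% or more in each control library. L7 replicate 3 alone cannot account for that share. The class median, which weighs each gene alike, does not settle carry-over for the genes with most of these reads. CT010467.1, annotated as ribosomal RNA, moved with the share. It was at 105, 62.3 and 69.0 FPKM in control and 28.2, 24.8 and 18.7 FPKM in L7 libraries. Carry-over of ribosomal RNA thus stays open, and the part of the share that each gene carries was not computed.

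L7 replicate 3 stood apart in muscle fibre genes. Its adult fast sarcomere median lay 1.96 ± 0.15 (SE over members) above the other L7 libraries' mean on the median of ratios scale. The medians of mitochondrial transcripts and histone genes lay 1.33 and 1.44 above that mean, though mt-Co2 was lower. A shallow library is argued against by a depth of 0.98 times the mean of the others, and the sex of the animal by a gap of 1.84 in that list to the nearest other library without Y-linked reads. A larger share of mature fibre as the only cause was predicted to lower all 6 lists chosen for that test. Macrophage, neutrophil, cell cycle, matrix and inflammatory genes were lower, at -0.76, -1.65 ± 0.32, -0.95, -0.35 and -0.85. Only fibro-adipogenic genes were higher, at 0.48 ± 0.22, so the prediction was not met. On FPKM as deposited that list was at 0.05, against -0.16 and 0.01 in L7 replicates 1 and 2. The test thus turns on a single list and its scaling, and leaves this explanation undecided. Lists outside the test lay higher still, such as adipocyte genes at 0.83 and erythroid and platelet genes at 1.51. A difference in the stage or extent of the injury in this muscle was not tested and stays open.

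For the lower interferon response genes, L7 replicate 3 alone is argued against by a median relative to all genes of -0.53 ± 0.044 (SE over members) without that library. Fewer macrophages are argued against by a macrophage median of 0.06 ± 0.067 in the same libraries, and sex by a median of -0.49 ± 0.029 with the sex covariate. Members moved together, with estimated correlations of 0.74 (macrophage) and 0.75 (interferon). These standard errors therefore do not measure the spread between libraries. By library, on the median of ratios scale, macrophage genes were at 0.14 and -0.07 in L7 replicates 1 and 2, within the control range of -0.23 to 0.32. Fewer T and NK lymphocytes or dendritic cells were not tested as a cause and stay open, since without L7 replicate 3 their list medians were -0.15 and -0.35. L7 replicate 2 alone, though, had them at 0.11 and 0.36 above the control mean with interferon genes at -0.51. L7 replicate 1 had them at -0.53 and -0.94 with interferon genes at -0.47. An effect of Linc-smad7 gain of function and a difference in the response to the injected plasmid preparations were not tested apart and stay open.

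With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split gave 873 genes at an unadjusted p under 0.05 and the highest other split gave 778, so 1 of the 10 splits gave as many. At an adjusted p under 0.05 the real split gave 0 genes, and the split that parts the 3 libraries without Y-linked reads from the others gave 6. Sex-linked genes differ in that split by its definition, so its 6 calls are not a fair comparison with the real split. The genes called there are not named here. For gene lists the real split called 13 and the highest other split called 21, and 9 of the 10 splits called at least as many.

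Whether reads of Novel00250 and Gm20544 come from 1 transcribed region cannot be told apart from 2 separate genes that both differ between the groups. Novel00250 ranked 2 of 14787 genes by its correlation with Gm20544 over the 6 libraries, and 2529 once the group means were removed, and it has no coordinates here. The hypothesis that genes with a miR-125b site are higher in L7 libraries, as binding of that microRNA would give, did not reach the bound set for it. Their length-adjusted difference of 0.045 exceeded that of 86 of 100 control 7-mers of the same bases, under the 95 set beforehand.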
